A study of Pan troglodytes with 8 samples.

How the data were processed

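Cerebral organoids were grown from SandraA, a chimpanzee (Pan troglodytes) induced pluripotent stem cell line. They were collected at week 8 of culture, within a window of 3 days either side, and dissociated cells were separated by fluorescence-activated sorting. The 4 sorted populations, each with 2 libraries, are abbreviated aRG (radial glia of the apical kind), bRG (those of the basal kind), bIP (intermediate progenitors, basal) and N (BCL11B-positive neurons). Per the labels' protocols, RNA from 10000 cells was reverse-transcribed and amplified with 12 to 17 PCR cycles in a Smart-seq2 type workflow, and amplified cDNA was fragmented with a transposome. Neither step marks the strand of origin, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The labels name no molecular identifiers, so counts include PCR copies, and floors on zero counts cover counting error only.

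The deposited values are whole-number read counts per gene symbol, 1 table on each of 2 genomes. Per the submitters' processing notes, STAR was used and the genome builds were panTro6 (chimpanzee) and hg38 (human). The STAR version, the gene annotation, the counting program and its strand setting are not given in the sources used here. The chimpanzee table held 60583 named rows and the human one held 18137, and each of these 18137 symbols was also in the chimpanzee table. In the chimpanzee table counts of 2 (21576 values) were more frequent than counts of 1 (16443), and counts of 4 (12294) more frequent than counts of 3 (9721). The human table showed no such preference for even counts (3442 values of 1 and 2632 of 2). Over shared symbols the chimpanzee totals were 1.70 to 1.74 times the human totals, so the chimpanzee counts may include both mates of a pair and were also tested after halving. The chimpanzee table has a row with no gene name, holding 0.00545% to 0.00771% of each library's counts, which was left out of library sizes and tests. All columns of both tables were matched to a labelled sample. Before the data were examined, the chimpanzee table was set as the main table provided that it named at least 80% of the genes in the fixed lists. It named 502 of 503 (99.8%).

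Library totals on the chimpanzee genome were 24649971 to 33245892 counts. Genes were filtered with filterByExpr, which left 35382, and scaled by the trimmed mean of M values (TMM). A single negative binomial model with a coefficient per population and 4 residual degrees of freedom was fitted to the 8 libraries with the quasi-likelihood method of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The common biological coefficient of variation was 0.629. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are TMM-scaled CPM (read counts relative to library size) as mean ± SD over 2 libraries. The labels do not say whether the libraries of a population came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Libraries of a population differed by 46.7 to 73.5 times the chi-square per gene of counting noise, a spread that does not show whether they came from separate RNA.

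Fixed before the data were examined were 27 gene lists covering cell identities, cell types that a gate could also admit, the cell cycle, signalling, adhesion, cell shape and stress. Each was tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. An estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, served as alternatives. For each list the numbers of members past the threshold were counted over all genes and adjusted over the list alone. In 4 main comparisons the named genes were the 8 with the largest rise and the 8 with the largest fall past the threshold. They needed a mean of at least 10 CPM in the higher population, both libraries of one population above both of the other, and a regular gene symbol. To these were added the members of each described list with the smallest adjusted p, 6 identity genes, and up to 6 genes per population-specific set. A gene was population-specific when it was higher than in each of the 3 other populations. For a gene at 0 in both libraries of a population, the bound on its fold uses a floor of 3 counts in each library and the mean of the other population.

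The same 8 libraries were compared between genomes as a log2 ratio of CPM per gene and library, with 1 CPM added to both. Ratios covered 15123 shared symbols with a mean of at least 1 CPM in either table, and a gene differed when the ratio passed 1 in the same direction in all 8 libraries. Whether a locus overlaps another gene was read from RefSeq genes of another chimpanzee assembly (NHGRI_mPanTro3-v2.0), used for neighbours only.

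The model was tested on simulated counts for the real genes, in which known changes were placed. Simulating bRG against aRG (32482 genes), the fit recovered 0 of 67 genes changed 2-fold, 25 of 67 (37.3%) changed 4-fold and 47 of 66 (71.2%) changed 8-fold, with 4 false calls among 76. Alternatives planned before the data were examined were the human genome table, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, the replicate number as a block, fits of only the populations compared, and each library left out in turn. Alternatives chosen after seeing the data were halved counts, only the symbols shared by both tables, a minimum of 5 CPM in 2 libraries, and robust estimation. Within-number medians compare libraries that carry the same replicate number and are on the log2(CPM + 1) scale, which draws differences of genes at few CPM towards 0.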

Results

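Gene expression was measured in 4 cell populations sorted from chimpanzee cerebral organoids at week 8. Apical radial glia are the neural stem cells that line the ventricle. Basal radial glia are stem cells that have left the ventricular surface, basal intermediate progenitors are transit-amplifying cells, and the neurons were those positive for BCL11B, a deep-layer transcription factor. The series title places the experiment in work on shape-regulating gene signatures of basal radial glia in neocortex evolution. Each population had 2 libraries. Totals on the chimpanzee genome were 24649971 and 33245892 counts for aRG, 28800481 and 28865049 for bRG, 25888197 and 24707801 for bIP, and 30320577 and 25324812 for N.

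Identity transcripts differed between the sorted populations. SOX2, a neural stem cell transcription factor, was at 904 ± 76.3 CPM in aRG and 587 ± 155 in bRG, against 77.9 ± 7.45 in bIP and 18.4 ± 9.36 in N (mean ± SD, n = 2 here and below). PAX6, a dorsal progenitor factor, stood at 193 ± 49.0, 161 ± 21.7, 111 ± 14.9 and 10.7 ± 6.59 CPM in the same order. EOMES, the transcription factor of intermediate progenitors, was at 1449 ± 129 CPM in bIP, 137 ± 66.3 in aRG, 85.4 ± 51.4 in bRG and 21.1 ± 14.3 in N. BCL11B was highest in N at 539 ± 71.6 CPM, then 317 ± 43.4 in bIP, 86.3 ± 38.5 in bRG and 58.4 ± 22.0 in aRG. HOPX, widely used as a marker of basal radial glia, was at 45.8 ± 5.52 CPM in aRG and 30.8 ± 3.70 in bRG. PROM1, which encodes an apical membrane protein, was at 63.4 ± 1.03 CPM in aRG and 51.7 ± 14.1 in bRG.

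**Figure D1:**
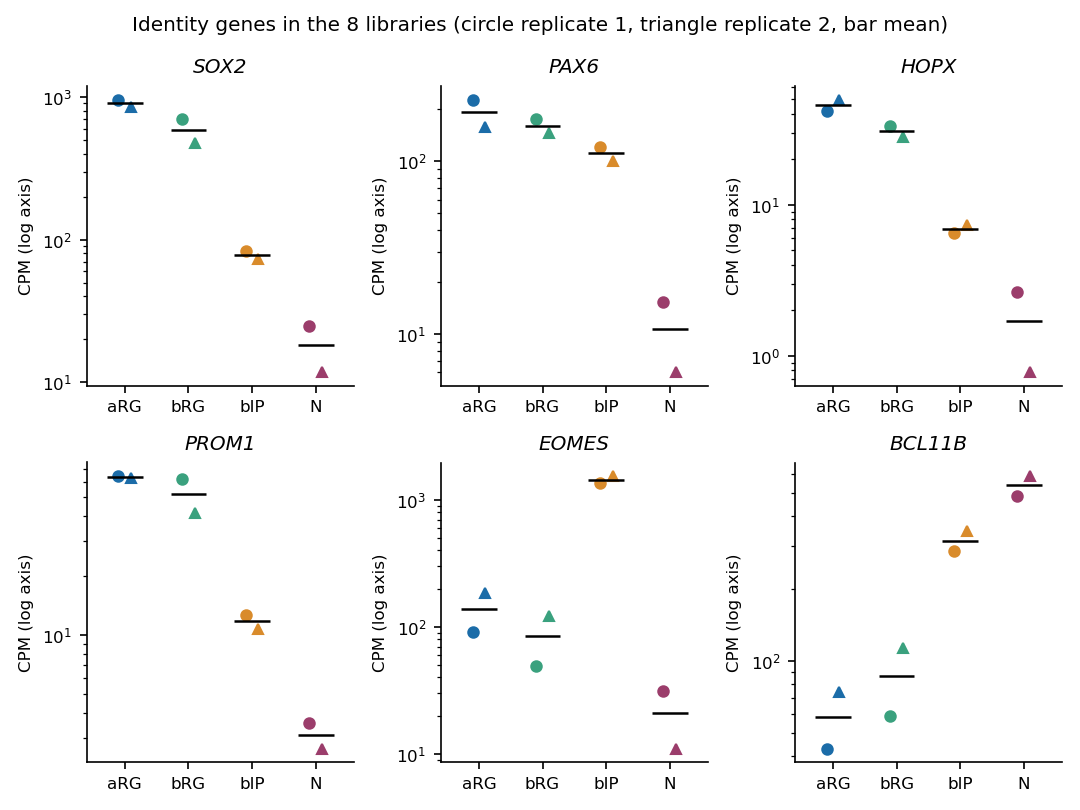
TMM-scaled CPM (log axis) of 6 identity genes in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and bars for population means. EOMES peaks in bIP at 1449 CPM and BCL11B in N at 539 CPM, while HOPX lies at 45.8 CPM in aRG and 30.8 in bRG.

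The first principal component of the filtered genes held 30.4% of the variance and ordered the populations from aRG through bRG and bIP to N. The third component held 14.2% and separated the 4 libraries numbered 1 from the 4 numbered 2. The share of counts from MALAT1, an abundant nuclear RNA, was higher in the library numbered 1 of every population, at 7.52% against 3.61% in aRG, 7.33% against 4.90% in bRG, 8.57% against 6.47% in bIP and 8.51% against 6.37% in N. For this reason list medians in the 4 main comparisons are also given within each replicate number.

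Between basal and apical radial glia edgeR called 1 gene and DESeq2 114, and camera called 1 list, of choroid plexus genes, with both correlations. The mitosis list was called lower in bRG with the preset correlation only (adjusted p = 0.0547 with an estimated correlation, 0.107 with fry). Of its 26 genes edgeR called 0, where 24 were lower at an unadjusted p under 0.05, and DESeq2 called 5 lower (UBE2C, CCNB1, TOP2A, CDC20 and MKI67). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, was at 61.8 ± 0.396 CPM against 174 ± 0.346 in aRG (edgeR adjusted p = 0.357, DESeq2 0.00176), and TOP2A, which untangles chromosomes, at 425 ± 32.5 against 1031 ± 194 (0.53 and 0.0212). The general neuronal list was called higher in bRG, also with the preset correlation only (adjusted p = 0.198 with an estimated correlation, 0.316 with fry). Of its 24 genes edgeR called 0, where 13 were higher at an unadjusted p under 0.05, and DESeq2 called 5 higher (GRIA2, SNAP25, L1CAM, SYT4 and SYN1). GRIA2, a glutamate receptor subunit, was at 159 ± 66.2 CPM against 33.1 ± 11.5 (edgeR adjusted p = 0.336, DESeq2 3.90e-05). TTR, a thyroid hormone carrier made by choroid plexus epithelium, was at 42.3 ± 8.75 CPM in bRG and 1955 ± 1608 in aRG. Transcripts of the basal radial glia list itself were not higher in bRG.

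Of 35382 genes tested with edgeR, TTR was the only one past the threshold between bRG and aRG (log2 fold change −5.53, SE 0.56, adjusted p = 0.0138). At an unadjusted p under 0.05 there were 1318 genes. If no gene differed, a share of 0.05 of the 35382 would be expected there, which is more. The call of TTR was lost when only these 2 populations were fitted (adjusted p = 0.786) and with a minimum of 5 CPM in 2 libraries (adjusted p = 0.114). DESeq2 called 114 genes and edgeR with no low-count filter 215. The human genome table, DESeq2 size factors and halved counts each gave 1. With no filter edgeR called the collagen COL1A1 (adjusted p = 1.22e-10), although its 2 aRG libraries were at 155 and 941 CPM. P-values and counts of that setting therefore need not reflect the spread between libraries. Of 27 lists 15 were called, 1 of them also with an estimated correlation, and 8 were called without aRG replicate 2.

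Of 26 mitosis genes, 0 passed over all genes by edgeR, against 5 by DESeq2 and 13 by edgeR with no low-count filter, and 24 were lower in bRG adjusted over the list alone. The list median was −1.16, with −1.25 and −1.02 within replicate numbers 1 and 2 (camera adjusted p = 1.47e-46, and adjusted p = 0.0547 with an estimated correlation). CCNB1, the mitotic cyclin, had a log2 fold change of −1.28 (SE 0.26, adjusted p = 0.53 by edgeR, 0.0159 by DESeq2 and 0.00900 with no filter), and UBE2C −1.49 (SE 0.26, adjusted p = 0.357, 0.00176 and 0.00160 in the same order). The list of 25 DNA replication genes was not called (median −0.12, with −0.11 and −0.13 within numbers, camera adjusted p = 0.221). The list of general neuronal genes had a median of 1.05 over 24 members, with 0.78 and 0.99 within replicate numbers 1 and 2 (camera adjusted p = 3.97e-21, and adjusted p = 0.198 with an estimated correlation). Of its members 0 passed over all genes by edgeR, against 5 by DESeq2 and 10 with no low-count filter, and 11 were higher adjusted over the list alone. With the human genome table, DESeq2 size factors, halved counts, shared symbols or robust estimation, 0 members of this list and 0 of the mitosis list passed. SNAP25, a synaptic vesicle fusion protein, had a log2 fold change of 2.31 (SE 0.47, adjusted p = 0.53 by edgeR and 0.00213 by DESeq2). L1CAM, an axonal adhesion molecule that DESeq2 also called, was at 1.68 (SE 0.35, adjusted p = 0.53 by edgeR and 0.00989 without bRG replicate 1). Deep-layer neuron genes had a median of 0.49 over 16 members, 6 of them higher adjusted over the list alone (0.18 and 0.55 within numbers, camera adjusted p = 3.61e-05, and adjusted p = 0.198 with an estimated correlation). Over all genes 0 of them passed by edgeR and 0 by DESeq2, against 5 with no low-count filter. TBR1, a deep-layer transcription factor, was at 79.8 ± 41.9 CPM in bRG and 26.5 ± 16.2 in aRG (adjusted p = 0.731).

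Lists of radial glia identity were called lower in bRG than in aRG with the preset correlation only, and fry called 0 lists in this comparison. At an unadjusted p under 0.05, 3 of 14 shared radial glia genes and 0 of 22 basal radial glia genes were lower. Genes shared by all radial glia had a median of −0.40 over 14 members (−0.31 and −0.51 within numbers 1 and 2, camera adjusted p = 2.26e-05, and adjusted p = 0.198 with an estimated correlation). The basal radial glia list had a median of −0.26 over 22 members (−0.30 and −0.22 within numbers, camera adjusted p = 0.00759, and adjusted p = 0.321 with an estimated correlation). The 49 regulators of actin, membrane and cell shape had a median of −0.28 (−0.18 and −0.29 within numbers, camera adjusted p = 4.29e-05, and adjusted p = 0.198 with an estimated correlation), and 0 of them passed adjusted over the list alone. Intermediate progenitor genes had a median of −0.27 over 22 members (−0.30 and −0.26 within numbers, camera adjusted p = 0.0153, and adjusted p = 0.479 with an estimated correlation). Without aRG replicate 2 the calls of the basal radial glia, cell shape and intermediate progenitor lists were lost (adjusted p = 0.388, 0.180 and 0.324). Without bRG replicate 1 those of the basal radial glia and intermediate progenitor lists were lost (adjusted p = 0.206 and 0.351).

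Choroid plexus transcripts moved with the aRG population. Of 14 choroid plexus genes 1 passed over all genes by edgeR, namely TTR, against 4 by DESeq2 (TTR, TRPM3, IGFBP7 and CLIC6) and 4 with no low-count filter (TTR, HTR2C, TRPM3 and CLIC6), and 10 were lower in bRG adjusted over the list alone. The list median was −2.10, with −1.08 and −1.95 within replicate numbers, and this was the only list of the comparison called with both correlations (camera adjusted p = 1.88e-21, and adjusted p = 0.0399 with an estimated correlation), though not with fry (0.0987). Of 13 cortical hem genes 1 passed, again TTR, which both lists hold (median −0.68, with −0.42 and −0.98 within numbers, camera adjusted p = 6.81e-10, and adjusted p = 0.168 with an estimated correlation). TRPM3, a cation channel, was at 80.6 ± 19.6 CPM in aRG and 16.6 ± 0.111 in bRG (adjusted p = 0.612 by edgeR, 0.00560 by DESeq2 and 7.29e-07 with no filter). Mesenchymal, vascular and immune genes had a median of −0.92 over 18 members, with 4 lower adjusted over the list alone (−0.37 and −0.44 within numbers, camera adjusted p = 0.000344, and adjusted p = 0.198 with an estimated correlation), a call lost without aRG replicate 2 (adjusted p = 0.319). COL1A1, the fibrillar collagen of mesenchyme, was at 155 CPM in aRG replicate 1 and 941 in aRG replicate 2. With no filter edgeR called it all the same (adjusted p = 1.22e-10), so p-values of that setting, as for TRPM3, need not reflect such spread.

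**Figure D2:**
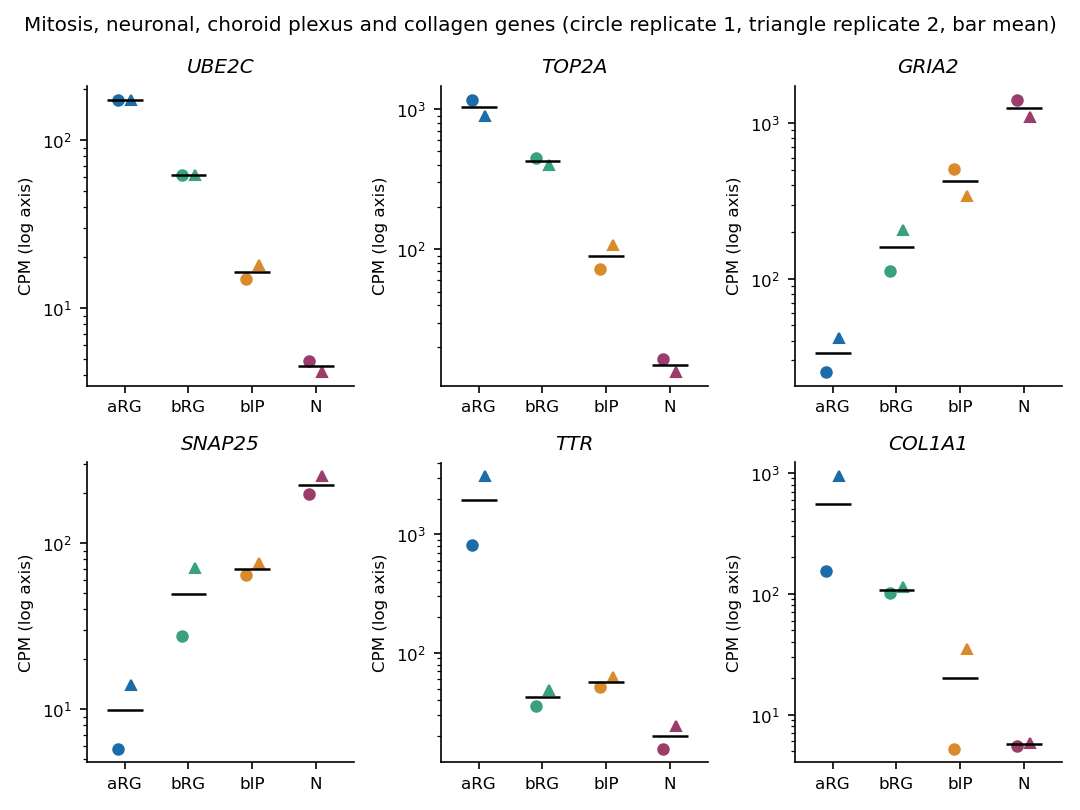
TMM-scaled CPM (log axis) of 6 genes in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and bars for population means. UBE2C and TOP2A are lower in both bRG than in both aRG libraries, GRIA2 and SNAP25 higher, and COL1A1 is at 155 and 941 CPM in the aRG libraries.

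Intermediate progenitors differed from apical radial glia by gain of intermediate progenitor and neuronal transcripts and loss of stem cell and mitosis transcripts. DLL3, a Notch ligand family member, rose from 14.0 ± 3.48 CPM in aRG to 351 ± 199 in bIP (log2 fold change 4.65, SE 0.50, adjusted p = 0.000606). PLXNA4, a semaphorin receptor, rose from 34.2 ± 10.0 to 726 ± 270 CPM (4.41, SE 0.51, adjusted p = 0.000848), and NPTX1, a synaptic pentraxin, from 25.9 ± 8.59 to 475 ± 217. HES1, the Notch effector that maintains progenitors, fell from 300 ± 104 to 18.1 ± 6.82 CPM (−4.05, SE 0.40, adjusted p = 0.000539). CDC20, an activator of the anaphase-promoting complex, fell from 258 ± 62.0 to 13.9 ± 4.60 CPM (−4.22, SE 0.34, adjusted p = 0.000306).

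edgeR called 1002 genes between bIP and aRG, 473 higher and 529 lower in bIP. The other leading rises were KLHL35 (log2 fold change 4.65), PPP1R16B (4.56), XKR7 (4.21), EBF2, a transcription factor of early neuronal differentiation (4.21), and FSTL5 (4.13). The other leading falls were FOS (−5.18) and EGR1 (−4.33), which are immediate early genes, TTR (−5.09), the collagens COL3A1 (−5.05) and COL1A1 (−4.78), TNFRSF12A, a TWEAK receptor (−4.76), and PIF1, a DNA helicase (−4.63). COL3A1 stood at 56.3 CPM in aRG replicate 1 and 554 in aRG replicate 2, and its call was lost without aRG replicate 2 (adjusted p = 0.107) and without bIP replicate 1 (adjusted p = 0.0538). The count was 582 without bIP replicate 2, and DESeq2 called 2282.

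Of 26 mitosis genes 25 fell in bIP, over all genes and adjusted over the list alone, with a median of −3.24 (−3.37 and −2.84 within replicate numbers, camera adjusted p = 1.75e-103). TOP2A fell by 3.52 on the log2 scale (adjusted p = 0.000306). Of 25 DNA replication genes 9 fell over all genes and 18 adjusted over the list alone (camera adjusted p = 9.53e-17, and adjusted p = 0.0658 with an estimated correlation), led by RRM2, a ribonucleotide reductase subunit (−2.50, SE 0.34, adjusted p = 0.00212). Of 14 shared radial glia genes 9 fell, and 12 adjusted over the list alone, with a median of −1.99 (−1.90 and −2.16 within numbers, camera adjusted p = 4.51e-33). SOX2 fell by 3.54 on the log2 scale (SE 0.36, adjusted p = 0.000539), and VIM, the intermediate filament of radial glia, fell by 2.91 (SE 0.29, adjusted p = 0.000539). In the basal radial glia list 7 of 22 fell, and 12 adjusted over the list alone, among them FAM107A (−3.09, SE 0.36) and HOPX (−2.73, SE 0.47). Their median was −1.29 (−1.41 and −1.13 within numbers, camera adjusted p = 2.34e-11).

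Of 22 intermediate progenitor genes 11 rose in bIP and none fell, and 17 rose adjusted over the list alone (median 1.76, with 1.78 and 1.74 within numbers, camera adjusted p = 4.78e-23). SSTR2, a somatostatin receptor, rose by 3.81 on the log2 scale (SE 0.51, adjusted p = 0.00191), and SOX11 and SOX4, transcription factors of early neurogenesis, by 2.08 and 1.61. General neuronal genes included 15 rises among 24, and 19 rises and 1 fall adjusted over the list alone (median 1.95, with 2.05 and 1.60 within numbers, camera adjusted p = 2.72e-30). RBFOX3, a neuronal splicing factor, rose by 3.00 (SE 0.32, adjusted p = 0.00057). Of 16 deep-layer genes 8 rose and 1 fell, and 10 rose and 3 fell adjusted over the list alone (median 2.07, with 1.94 and 1.94 within numbers, camera adjusted p = 2.53e-09). SLC17A6, a vesicular glutamate transporter, rose by 3.33 (SE 0.34, adjusted p = 0.000539) and TBR1 by 3.37 (SE 0.45, adjusted p = 0.00195).

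Signalling and matrix genes moved as well. Among 21 Notch genes 6 fell and 1 rose, and 9 fell and 4 rose adjusted over the list alone (median −0.48, with −0.35 and −0.27 within numbers, camera adjusted p = 0.000249), where NOTCH3, a receptor, fell by 2.80 on the log2 scale and DLL3 was the riser. Of 24 Wnt genes 5 fell, and 10 adjusted over the list alone (median −0.88, with −0.63 and −0.98 within numbers, camera adjusted p = 4.84e-09), led by the receptor FZD8 (−3.19, SE 0.33). Of 29 matrix and integrin genes 7 fell, and 16 fell and 1 rose adjusted over the list alone (median −1.19, with −0.91 and −1.33 within numbers, camera adjusted p = 6.41e-13, and adjusted p = 0.0533 with an estimated correlation). SPARC, a matrix glycoprotein, fell by 3.51 (SE 0.31, adjusted p = 0.000421). Lists of other cell types and regions were called lower in bIP as well. Of 14 choroid plexus genes 5 fell, and 8 adjusted over the list alone (median −2.86, with −1.59 and −2.47 within numbers, camera adjusted p = 2.21e-12, and adjusted p = 0.0455 with an estimated correlation). Of 13 cortical hem genes 3 fell, and 11 adjusted over the list alone (median −2.87, with −2.07 and −2.23 within numbers, camera adjusted p = 2.82e-13, and adjusted p = 0.0476 with an estimated correlation). Of 18 mesenchymal, vascular and immune genes 3 fell, and 6 adjusted over the list alone (median −0.44, with −0.36 and −0.55 within numbers, camera adjusted p = 0.00258, and adjusted p = 0.169 with an estimated correlation). That list holds COL1A1 and COL3A1, at 155 and 56.3 CPM in aRG replicate 1 and at 941 and 554 in aRG replicate 2. Of 49 cell shape regulators 7 fell, and 15 fell and 3 rose adjusted over the list alone (median −0.46, with −0.24 and −0.57 within numbers, camera adjusted p = 7.26e-05, and adjusted p = 0.138 with an estimated correlation). In all, 20 of 27 lists were called and 11 of these also with an estimated correlation.

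**Figure D3:**
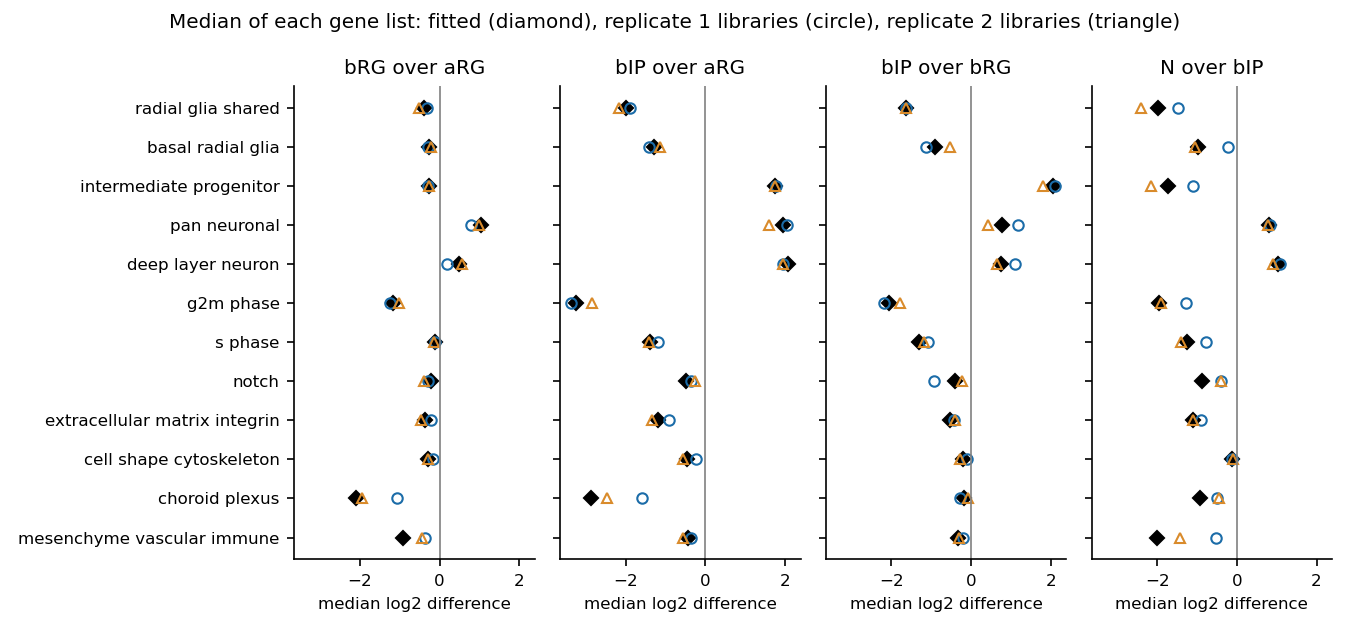
Median log2 difference of 12 gene lists in the 4 main comparisons, with diamonds for the fitted fold changes of both replicate numbers, circles for libraries numbered 1 and triangles for libraries numbered 2 (log2(CPM + 1)). The mitosis list lies at −1.16 in bRG over aRG, −3.24 in bIP over aRG, −2.07 in bIP over bRG and −1.94 in N over bIP.

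Intermediate progenitors and basal radial glia differed in intermediate progenitor, mitosis and shared radial glia transcripts. EOMES rose from 85.4 ± 51.4 CPM in bRG to 1449 ± 129 in bIP (log2 fold change 4.08, SE 0.56, adjusted p = 0.00684). NHLH1, a neurogenic transcription factor, rose from 44.6 ± 7.39 to 629 ± 129 CPM (3.82, SE 0.66, adjusted p = 0.0181). ETV5, a transcription factor downstream of fibroblast growth factor signalling, fell from 123 ± 19.0 to 9.10 ± 6.22 CPM (−3.76, SE 0.51, adjusted p = 0.00684). ZFP36L1, an RNA-binding protein that destabilises transcripts, fell from 596 ± 279 to 59.0 ± 4.11 CPM (−3.34, SE 0.39, adjusted p = 0.00547).

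edgeR called 365 genes between bIP and bRG, 162 higher and 203 lower in bIP. The other leading rises were RBM43P1, a pseudogene whose reads may be shared with its parent gene (log2 fold change 4.62), EBF2 (4.26), ADCYAP1, a neuropeptide (4.15), PLXNA4 (4.08), KLHL35 (3.91) and DLL3 (3.66). The other leading falls were FOS (−4.96), TNFRSF12A (−3.76), OAF (−3.55), EGR1 (−3.46), BST2 (−3.38) and AHNAK, a large membrane scaffold (−3.30). The count was 209 without bIP replicate 1, 140 without bIP replicate 2 and 241 without bRG replicate 1, and DESeq2 called 1167. Without bIP replicate 2 the calls of RBM43P1, EBF2, TNFRSF12A, OAF, EGR1, BST2 and AHNAK were lost (adjusted p = 0.0597 to 0.186). Without bIP replicate 1 those of OAF, EGR1 and BST2 were lost (0.154 to 0.157), and without bRG replicate 1 those of RBM43P1, EGR1 and AHNAK (0.0532 to 0.110).

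Of 22 intermediate progenitor genes 12 rose, and 20 adjusted over the list alone (median 2.05, with 2.11 and 1.81 within numbers, camera adjusted p = 2.72e-42). NEUROG2, a proneural transcription factor, rose by 1.78 on the log2 scale (SE 0.28, adjusted p = 0.012). Of 26 mitosis genes 19 fell, and 25 adjusted over the list alone (median −2.07, with −2.19 and −1.78 within numbers, camera adjusted p = 4.15e-65), among them BUB1, a spindle checkpoint kinase (−2.29, SE 0.32, adjusted p = 0.0069). Of 14 shared radial glia genes 7 fell, and 12 adjusted over the list alone (median −1.64, with −1.64 in both numbers, camera adjusted p = 1.97e-30), with SOX2 at −2.91 (SE 0.35) and TTYH1 at −2.37 (SE 0.26). These 3 lists were the ones also called with an estimated correlation, among 16 called. General neuronal genes included 4 rises among 24, and 12 rises and 1 fall adjusted over the list alone (median 0.78, with 1.17 and 0.42 within numbers, camera adjusted p = 8.75e-12, and adjusted p = 0.151 with an estimated correlation). MAP2, a dendritic microtubule protein, rose by 1.44 (SE 0.26, adjusted p = 0.0243). In the basal radial glia list 4 of 22 fell, and 9 adjusted over the list alone (median −0.91, with −1.13 and −0.53 within numbers, camera adjusted p = 3.87e-09, and adjusted p = 0.112 with an estimated correlation), namely FAM107A, BMP7, PTN and TKTL1 over all genes. Without bIP replicate 1 the calls of NEUROG2, BMP7, PTN and TKTL1 were lost (adjusted p = 0.0519 to 0.237), without bIP replicate 2 those of BUB1, MAP2 and TKTL1 (0.0535 to 0.237), without bRG replicate 1 those of NEUROG2, MAP2 and TKTL1 (0.0545 to 0.220), and without bRG replicate 2 that of TKTL1 (0.0665).

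Between neurons and intermediate progenitors, camera called the intermediate progenitor and mitosis lists lower in N and the general neuronal list higher, with the preset correlation only (adjusted p = 0.0856, 0.0856 and 0.251 with an estimated correlation). EOMES fell from 1449 ± 129 CPM in bIP to 21.1 ± 14.3 in N (log2 fold change −6.10, SE 0.62, adjusted p = 0.000398). NEUROG1, a proneural transcription factor, was at 59.6 ± 27.0 CPM in bIP and at 0 counts in both N libraries (edgeR adjusted p = 0.000152). The bIP mean was 486 times the floor of 3 counts in each N library. This bound leaves out the spread of bIP, whose libraries were at 78.7 and 40.4 CPM. GABBR2, a subunit of the metabotropic GABA receptor, rose from 13.2 ± 0.157 to 308 ± 94.4 CPM (4.54, SE 0.68, adjusted p = 0.00439). GRIK3, a kainate receptor subunit, rose from 8.74 ± 3.40 to 178 ± 148 CPM (4.35, SE 0.73, adjusted p = 0.00785).

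edgeR called 900 genes between N and bIP, 376 higher and 524 lower in N. The other leading rises were TMPRSS13 (log2 fold change 4.84), CLEC2L (4.37), ARHGAP20 (4.35), RASGEF1A (4.33), KCNQ5, a potassium channel (4.24), and VSTM2L (4.14). The other leading falls were NEUROD4, a neurogenic transcription factor (−6.29), EBF2 (−5.67), SLC4A11 (−5.31), RRM2 (−4.97), MFNG, a Notch-modifying glycosyltransferase (−4.91), and EPHA3, an ephrin receptor (−4.87). The count was 415 without bIP replicate 2, 498 without N replicate 2 and 543 in a fit of these 2 populations alone, and DESeq2 called 2577. Without bIP replicate 2 the calls of CLEC2L, RASGEF1A, KCNQ5 and SLC4A11 were lost (adjusted p = 0.0559 to 0.194), and without N replicate 2 those of CLEC2L, KCNQ5, SLC4A11 and EPHA3 (0.0535 to 0.276). Without bIP replicate 1 those of CLEC2L and KCNQ5 were lost (0.0531 and 0.108), and without N replicate 1 that of SLC4A11 (0.0884).

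Of 22 intermediate progenitor genes 10 fell in N, and 16 adjusted over the list alone (median −1.72, also with NEUROG1 at its bound, and −1.11 and −2.15 within numbers, camera adjusted p = 7.94e-24, and adjusted p = 0.0856 with an estimated correlation). Of 26 mitosis genes 16 fell, and 19 adjusted over the list alone (median −1.94, with −1.27 and −1.91 within numbers, camera adjusted p = 1.52e-37, and adjusted p = 0.0856 with an estimated correlation), where MKI67, the proliferation antigen, fell by 3.97 on the log2 scale (SE 0.36, adjusted p = 0.000252). General neuronal genes included 6 rises and 1 fall among 24, and 13 rises and 2 falls adjusted over the list alone (median 0.81, with 0.83 and 0.79 within numbers, camera adjusted p = 3.80e-08, and adjusted p = 0.251 with an estimated correlation). CNTN1, an axonal adhesion molecule, rose by 3.27 (SE 0.41, adjusted p = 0.00145), and MAPT, the microtubule protein tau, by 2.30 (SE 0.42, adjusted p = 0.0124). CNTN2, an adhesion molecule of early axons, fell by 2.52 (SE 0.46, adjusted p = 0.0127). Of 16 deep-layer genes 4 rose and 2 fell, and 8 rose and 4 fell adjusted over the list alone (median 1.04, with 1.08 and 0.90 within numbers, camera adjusted p = 0.00595, and adjusted p = 0.232 with an estimated correlation). FEZF2, which specifies subcerebral projection neurons, rose by 1.63 (SE 0.26, adjusted p = 0.0065), while ETV1 fell by 3.16 (SE 0.33, adjusted p = 0.000566). Of 31 primary cilium genes 1 rose, IFT122 (1.56, SE 0.26, adjusted p = 0.00837), and the list was higher (median 0.43, with 0.26 and 0.60 within numbers, camera adjusted p = 8.92e-05, and adjusted p = 0.13 with an estimated correlation). Of 29 matrix and integrin genes 8 fell, and 16 fell and 1 rose adjusted over the list alone (median −1.09, with −0.89 and −1.10 within numbers, camera adjusted p = 1.15e-12, and adjusted p = 0.113 with an estimated correlation), led by COL4A5 (−3.37, SE 0.25). Of 18 mesenchymal, vascular and immune genes 1 fell, PDGFRB, and 6 adjusted over the list alone (median −2.01, with −0.52 and −1.44 within numbers, camera adjusted p = 0.00117, and adjusted p = 0.187 with an estimated correlation). Further lists of other cell types were called lower in N. Of 9 Cajal-Retzius genes EBF2 and EBF3 fell and CALB2 rose (median −2.11, with −1.03 and −1.56 within numbers, camera adjusted p = 0.00322, and adjusted p = 0.113 with an estimated correlation). Of 11 astrocyte genes 1 fell, ALDH1L1 (median −1.62, with −0.89 and −0.39 within numbers, camera adjusted p = 0.00741, and adjusted p = 0.2 with an estimated correlation). Of 18 non-telencephalic genes IRX2 and LHX9 fell (median −1.36, with −0.38 and −0.34 within numbers, camera adjusted p = 0.0140, and adjusted p = 0.293 with an estimated correlation). For the mesenchymal, Cajal-Retzius, astrocyte and non-telencephalic lists the fitted median lay beyond both within-number medians, so members at few CPM may weigh on it. Without N replicate 2 the Cajal-Retzius and astrocyte calls were lost (adjusted p = 0.0812 and 0.0769), and without bIP replicate 1 the astrocyte and non-telencephalic calls (0.0752 and 0.126). Among these genes the calls of ALDH1L1, PDGFRB and IRX2 were lost without N replicate 2 (adjusted p = 0.0802, 0.0823 and 0.0589), IRX2 and LHX9 without bIP replicate 2 (0.167 and 0.0980), PDGFRB without bIP replicate 1 (0.123) and IRX2 without N replicate 1 (0.118). Without bIP replicate 2 the calls of MAPT, CNTN2, FEZF2 and IFT122 were lost (adjusted p = 0.0748 to 0.0894), and without bIP replicate 1 that of the deep-layer list (0.0669). In all, 18 lists were called and 0 of these with an estimated correlation.

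Neurons and the radial glia populations were the most different pairs. edgeR called 3421 genes between N and aRG, 1724 higher and 1697 lower in N, and 2128 between N and bRG, 928 higher and 1200 lower. The N and bRG count was 1190 without bRG replicate 1, 1389 without N replicate 2 and 1392 in a fit of these 2 populations alone. The median of the mitosis list was −5.11 in N over aRG and −3.80 in N over bRG (camera adjusted p = 6.21e-108 and 6.70e-96), and that of general neuronal genes 2.64 and 1.74 (camera adjusted p = 4.39e-33 and 9.24e-23, the latter with adjusted p = 0.0631 with an estimated correlation). Of 17 lists called in each, 10 held with an estimated correlation in N over aRG and 2 in N over bRG.

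Population-specific genes, higher than in each of the 3 other populations, numbered 241 in N, 36 in bIP, 1 in aRG and 0 in bRG by edgeR, where DESeq2 gave 595, 107, 21 and 0. For bRG, 3 genes were higher than in each other population at an unadjusted p under 0.05. Among the leading genes of N were KCNQ5-AS1, annotated as antisense to a potassium channel gene (counts here carry no strand), at 28.1 ± 21.3 CPM, ARPP21, at 268 ± 6.37 CPM, CACNA1E, a calcium channel, at 450 ± 241, MARCHF4 at 191 ± 19.7 and PLPPR4 at 68.0 ± 0.981. Those of bIP were EBF2 at 82.9 ± 63.1 CPM, ADCYAP1 at 33.4 ± 3.29, NHLH1, EOMES, RGS4, a regulator of G protein signalling, at 16.9 ± 10.3, and KLHL35 at 369 ± 188. The gene of aRG was TTR, a choroid plexus transcript. The N set numbered 88 without bIP replicate 2, 116 without N replicate 2 and 148 without bRG replicate 1, the bIP set 9 without bIP replicate 2, and the aRG set 2 without bRG replicate 1.

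For symbols in both tables, the same libraries counted on the human genome gave similar fold changes. Among symbols with a RefSeq locus, the human table held 1 on the X chromosome and 0 on the Y, against 759 and 17 in the chimpanzee table. X-linked genes were thus hardly covered by this comparison, and 17 genes of the fixed lists were absent from the human table. Across 15608 genes, which are not independent replicates, Pearson correlations of fold changes between the tables were 0.952 to 0.978 over the 6 comparisons. Of 15123 symbols compared, 793 were more than 2-fold higher on the human genome in all 8 libraries and 42 on the chimpanzee genome. SFPQ, a splicing factor, was at 1129 ± 173 CPM on the human genome (n = 8) and at 0 counts on the chimpanzee genome. MTRNR2L12, a nuclear copy of a mitochondrial sequence that can take up mitochondrial reads, was at 4551 ± 1216 CPM on the human genome and at 0 counts on the other, as was NPIPB15, a member of a segmentally duplicated family, at 630 ± 68.0 CPM. GABARAP, an autophagy protein, was at 282 ± 29.1 CPM on the chimpanzee genome and 1.30 ± 0.327 on the human genome, GSTT2 at 49.6 ± 8.53 and 2.86 ± 0.694, and CELF6 at 90.0 ± 82.1 and 4.46 ± 3.94. Of the genes in the fixed lists, 11 were among the 793 higher on the human genome, including NEFM, RAC3, LLGL1 and SESN2 at 0 counts on the chimpanzee genome, and these 4 did not enter the list tests.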

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

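The chimpanzee table contains a row without a gene name, which entered no comparison. It held between 1388 and 2222 counts per library, above the limit that a count of 0 allows, and is given as a value because its origin is not stated in the sources used here. No test of this row was planned or run.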

How the results depend on the processing

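Halved counts, the set of shared symbols, the minimum of 5 CPM and robust estimation were chosen after seeing the data, and the other alternatives before. Over all alternatives, values of single genes stayed on the same side of the threshold in 5626 cases, came to pass it in 324 and ceased to pass it in 211. Those of lists did so in 1234, 30 and 124. None past the threshold in the main fit changed direction, while directions of those not past it were not counted. The human genome table, DESeq2 size factors, halved counts and shared symbols left every count of genes, population-specific genes and lists within 1.5 times its value, as robust estimation did for genes and population-specific genes, the only counts it was run on. With an estimated correlation camera called 1 list in bRG over aRG, 11 in bIP over aRG, 3 in bIP over bRG, 0 in N over bIP, 10 in N over aRG and 2 in N over bRG. With fry there were 0 in bRG over aRG, 3 in bIP over bRG and 9 in N over bIP.

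The DESeq2 test called 114 genes in bRG over aRG (87 higher), 2282 in bIP over aRG, 1167 in bIP over bRG, 2577 in N over bIP, 5303 in N over aRG and 3835 in N over bRG, with 21 genes specific to aRG, 107 to bIP and 595 to N. Without the low-count filter there were 215 genes in bRG over aRG (168 higher), 2159 in bIP over aRG, 1187 in bIP over bRG, 2264 in N over bIP and 3280 in N over bRG, with 44, 113 and 637 genes specific to aRG, bIP and N. As COL1A1 showed, these counts need not reflect the spread between libraries. With the replicate number as a block there were 39 genes in bRG over aRG (31 higher), 2122 in bIP over aRG, 1121 in bIP over bRG, 2165 in N over bIP and 3594 in N over bRG, with 7, 101 and 749 genes specific to aRG, bIP and N. In bRG over aRG the block called 3 mitosis genes lower and 3 general neuronal genes higher. Whether libraries that share a number are paired is not established, so the block is given here only. Fits of only the populations compared, with fewer libraries, gave 0 genes in bRG over aRG by edgeR, 543 in N over bIP and 1392 in N over bRG. The minimum of 5 CPM gave 0 genes in bRG over aRG by edgeR, 0 specific to aRG and 58 specific to bIP. Beside these counts of 0 in bRG over aRG, 1304 and 671 genes had an unadjusted p under 0.05, and DESeq2 called 114. The 1304 were fewer than a share of 0.05 of the 31494 genes tested in the fit of only bRG and aRG. The causes of these differences between settings were not tested.

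With each library left out in turn, where the lone library is assumed to vary like the other groups, there were 1 to 85 genes in bRG over aRG (85 without bRG replicate 1) and 8 to 17 lists (8 without aRG replicate 2). There were 582 to 693 genes in bIP over aRG (582 without bIP replicate 2), 140 to 358 in bIP over bRG (140 without bIP replicate 2), 415 to 1150 in N over bIP (415 without bIP replicate 2) and 1190 to 1914 in N over bRG (1190 without bRG replicate 1). Specific genes numbered 1 to 2 in aRG (2 without bRG replicate 1), 9 to 53 in bIP (9 without bIP replicate 2) and 88 to 354 in N (88 without bIP replicate 2). The median log2 fold change of all genes tested was −0.11 in N over bRG, and DESeq2 size factors moved it by less than 0.1 in each comparison. At this depth and spread, 2-fold changes in bRG over aRG, simulated with few genes changed, were recovered by the main edgeR fit in 0 of 67 genes. That does not set a limit for the real data or for other settings. Among these, DESeq2 called PTTG1 at a log2 fold change of −1.18 (adjusted p = 0.0423).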

Other observations

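The tests of explanations for the 3 patterns weighed below were chosen after the results they measure had been seen, the overlap test of genome differences included. The list tests and the fits without a library were planned before.

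Stress and neuron subtype lists added further contrasts. Immediate early and heat shock genes were lower in bIP than in bRG, with 2 of 14 past the threshold, FOS and EGR1, and 5 adjusted over the list alone (median −0.70, with −0.91 and −0.52 within numbers, camera adjusted p = 4.18e-05, and adjusted p = 0.216 with an estimated correlation). FOS was at 61.0 and 37.2 CPM in the aRG libraries and at 48.3 and 36.2 in the bRG libraries, against 0.466 and 2.24 in bIP. Unfolded protein response genes were lower in bIP than in bRG, with 1 of 16 past the threshold, TRIB3, and 6 adjusted over the list alone (median −0.79, with −0.80 and −0.51 within numbers, camera adjusted p = 3.81e-07, and adjusted p = 0.115 with an estimated correlation). Upper-layer neuron genes were not called between N and bIP (camera adjusted p = 0.214), where PLXND1 and RORB rose and POU3F2 fell. Each of these 3 calls was lost without bIP replicate 2 (adjusted p = 0.0559, 0.138 and 0.439), those of RORB and POU3F2 also without N replicate 2 (0.0896 and 0.205), and that of RORB without bIP replicate 1 (0.0879). The calls of EGR1 and TRIB3 were lost without bIP replicate 1 (adjusted p = 0.155 and 0.105), without bIP replicate 2 (0.0830 and 0.0847) and without bRG replicate 1 (0.0820 and 0.0731). Lists of pluripotency, glycolysis and hypoxia, and oligodendrocyte precursor genes were called in none of the 6 comparisons with the preset correlation.

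In the first pattern weighed, neuronal transcripts in bRG, genes specific to N were chosen without 1 aRG library and compared with that library. Of 291 chosen without aRG replicate 1, 95.5% had a higher mean in bRG, as had 88.8% of 330 chosen without aRG replicate 2. Of 8713 genes not called between N and aRG and at a mean of 10 CPM or more in N, 49.3% and 40.9% were higher in bRG than in these libraries. The excess of the genes specific to N was 9.57% to 17.3% and 4.94% to 13.7% of the difference between N and aRG (quartiles over genes). With all libraries, 1480 genes at 10 CPM or more in N and called at least 2-fold higher in N than in aRG had an excess of 7.72% to 18.8%. The 1317 at 10 CPM or more in aRG and called at least 2-fold lower in N were lower in bRG by 15.5% to 44.7% of that difference. The excess depended on the library, since its median over the 241 genes specific to N was 6.41% within replicate number 1 and 14.9% within number 2. DESeq2 with all libraries called 87 genes higher in bRG. A candidate explanation is that neurons, or their RNA, made up part of the bRG libraries, although sorting by population should remove them. Such admixture alone would move both gene sets by a similar share of the difference between N and aRG. The fall of the 1317 genes (15.5% to 44.7%) was the larger share, against 7.72% to 18.8% for the rise of the 1480, with overlapping quartile ranges. Both sets were chosen with the same aRG libraries that bRG was then compared with. Choosing genes for a high aRG level can enlarge the fall, so the gap does not decide about admixture alone. It stays open for the fall and for the rise of neuronal transcripts. Passage of bRG through the intermediate progenitor state was expected to raise that list. Its median was −0.27 in bRG over aRG (bootstrap 95% interval over genes −0.50 to 0.02). Intermediate progenitors were sorted into a gate of their own, which could remove such a rise, so the median does not decide this. Low neuronal expression within bRG themselves also stays open, as bulk libraries do not separate it from admixed cells.

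Choroid plexus transcripts in aRG were the second. Of 14 choroid plexus genes, 12 had their highest population mean in aRG, including HTR2C at 16.0 and 72.4 CPM and TTR at 819 and 3092 CPM in the aRG libraries, which may reflect choroid plexus epithelium in that gate. Of these 14 genes, 7 were at 10 CPM or more in aRG and 2 in bRG, and 2 are also in another list. For TTR a single aberrant library is argued against as the cause. Without aRG replicate 2 its log2 fold change in bRG over aRG was still −4.27. Over all settings run, its adjusted p ranged from 1.74e-53 (no low-count filter) to 0.786 (only the 2 populations fitted). For the whole list the median was −1.08 within replicate number 1 and −1.95 within number 2, so part of the pattern may rest on aRG replicate 2. Patterning of apical cells near the choroid plexus stays open, as the cortical hem list, which bears on it, was lower in bRG than in aRG with the preset correlation only (median −0.68, camera adjusted p = 6.81e-10, and adjusted p = 0.168 with an estimated correlation) and shares TTR.

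Genes far higher on the human genome were the third. Of the 793 genes, 664 had a locus in RefSeq of another assembly, and 42.5% of these overlapped another gene against 47.0% of genes within 2-fold (Fisher's exact test, two-sided, p = 0.0231, in the opposite direction). Overlap with RefSeq genes was thus not more frequent among these 664, and for the other 129 it was not tested. Of 60583 named rows of the chimpanzee table, 18225 had a symbol in RefSeq. Overlap with the remaining rows could not be seen, so overlap as a cause stays open. Of the 793, 398 (50.2%) had exactly 0 counts in all 8 libraries on the chimpanzee genome, which could reflect gene models without a countable position. The remainder had counts, so that explanation cannot be the whole cause, and for the genes at 0 it stays open because the annotation used for counting is not given in the sources used here.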
